A study of Mus musculus with 8 samples.

How the data were processed

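Gene expression was measured by RNA sequencing in 8 libraries of mouse induced pluripotent stem cells (iPSCs), which are cells reprogrammed from fibroblasts to a state like that of the early embryo and which were grown over a layer of feeder cells. Per the labels, polyadenylated RNA was made into strand-specific libraries and sequenced on a HiSeq2500. The values used are FPKM (fragment counts scaled to transcript length and to the mapped fragments of the library), deposited by the authors as 1 table of 23284 gene symbols with 1 column per library. The submitters' processing notes name FastQC, TopHat2 2.0.10, Bowtie 1.0.0, SAMtools 0.1.19, Cufflinks 2.2.1 and Cuffnorm, and the builds GRCm38 and mm10. The version of Cuffnorm, its option for scaling libraries, the annotation release and the strand setting are not given in the sources used here. FPKM are shares of a library, so a rise of abundant genes lowers the values of others. Fragments that match near-identical genes are divided between them by estimation, and such genes are reported as uncertain.

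The depth in fragments is not given in the sources used here, so no counting intervals were computed. Relative depth was estimated from genes under 0.3 FPKM, whose values step by what 1 fragment is worth, as the most common ratio to the siControl library. It ranged from 92.3% to 100% of that library, but only 13.4% to 21% of these genes lay at the most common ratio in the other libraries, so the estimate is rough. The FPKM of a library summed to between 486917 and 586657, the highest sum being that of the double siRNA library.

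Groups were taken from the labels. The 4 libraries of wild-type iPSCs had 1 library per siRNA group, and the miR-203 knock-in line had 2 clones in each of 2 groups. Dox and vehicle libraries were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) on log2(FPKM + 1), over the 11927 genes with a mean FPKM of 1 or more in those 4 libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All fold changes are differences on the log2(FPKM + 1) scale, which understates the change of low genes. Only these 4 libraries entered the fit, because the siRNA libraries have no replicates and come from another line. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, with an estimated correlation and with fry as alternatives, and list p-values were adjusted over the lists tested. Both alternatives rest on the few residual degrees of freedom that 4 libraries leave. A call lost with them need not mean correlation between genes. The smallest list tested had 3 measured members.

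The siRNA libraries were compared with siControl as differences of log2(FPKM + 1), counting genes at 2-fold or more among those with a mean FPKM of 1 or more over the 2 libraries. The median of each list was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression. Such a percentile describes these libraries and is no p-value. For the correlation between siRNA comparisons, 100 simulations drew unchanged libraries against 1 shared control. The spread of each gene was taken from the limma fit of the knock-in libraries and was equal in all simulated libraries, which fixes the correlation in advance. Sites for miR-203 were matches of the seed (positions 2 to 8 of miR-203-3p) in the 3' UTRs of GENCODE mouse release M21 on GRCm38, which also gave gene positions, GC content and length. Its copy may be of another release than the authors' annotation. Of the 12042 genes with a mean FPKM of 1 or more over all 8 libraries, 99.1% were matched to it by symbol or synonym.

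The groups, tests, gene lists and the rule for naming genes were fixed before the data were examined. There were 17 lists with 491 entries, of which 485 were matched to the table, 7 of them through an older symbol, and 6 were not. Lists shared 5 members. Genes named are Dnmt1, Dnmt3a, Dnmt3b and Dnmt3l, the 10 largest differences per direction in each siRNA comparison and over all 3 together, the 12 largest per direction past the threshold for dox, and the 10 per direction with the largest smallest difference over the double siRNA and both clones. Up to 4 members with the largest difference were added from each list, or up to 6 where they passed the test. Small RNA genes (symbols in Mir, Snor, Scarna, Rnu or n-R5), predicted genes, clone names, pseudogene symbols and joined symbols were not named under this rule. Other non-coding RNA genes, such as Rpph1, could be named. A list of macrophage markers and every gene said to be outside the rule were chosen after their values were seen.

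The clone number was taken to pair a dox with a vehicle library, since the labels number the clones 1 and 2 in each group, but they do not state that equal numbers mean the same clone. Over the genes tested, the difference between clones in dox correlated with that in vehicle (Pearson r = 0.441, across genes, which are not independent replicates). The clone was not a term of the model, and a fit with it as a block was run as an alternative. On simulated values for the 11927 genes of the dox comparison, 200 genes were changed in total, split evenly between 4-fold and 2-fold changes. There limma recovered 100% of the 4-fold and 100% of the 2-fold changes with 20 false calls, and with the block 100% of each with 28 false calls. The simulated libraries had independent errors, with the SD that limma had fitted, and no clone effect. They therefore do not show how either fit performs where clones differ, nor which of them is the better choice here.

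Other alternatives were pseudocounts of 0.1 and 0.5, no filter on low values or a minimum of 5 FPKM, quantile and median-ratio scaling, a robust variance fit, each library left out in turn, 1.5-fold and 3-fold limits, and each clone alone. A correction for GC content and transcript length, alone and with the clone block, and siRNA counts without small RNA, predicted and pseudogene names were added after the data were seen. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.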

Results

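The transcriptome of mouse iPSCs was measured in 8 polyA RNA libraries. Wild-type iPSCs were transfected with a control siRNA (siControl), with siRNA against Dnmt3a, with siRNA against Dnmt3b, or with both (the double siRNA), and were collected 1 week later, with 1 library per group. A second iPSC line carried miR-203, a microRNA of differentiating epithelia, as a knock-in under doxycycline (dox) control. Its clones 1 and 2 were given dox for 5 days and collected 2 weeks after withdrawal, beside vehicle libraries of clones with the same numbers (n = 2 per group). Between 11620 and 12076 genes per library had 1 FPKM or more. The siRNA comparisons have no replicate check and no p-value, and p-values of the dox comparison measure only the spread between these 4 libraries.

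The siRNA targets were measured first. Dnmt3a and Dnmt3b encode the enzymes that set new DNA methylation, Dnmt3l their cofactor without catalytic activity, and Dnmt1 the enzyme that maintains methylation. On GRCm38, Dnmt3a lies on chromosome 12 from 3806007 to 3914443 (plus strand), and Dnmt3b on chromosome 2 from 153649450 to 153687730 (plus strand). Dnmt3l lies on chromosome 10 from 78041947 to 78063622 (plus strand), and Dnmt1 on chromosome 9 from 20907209 to 20959888 (minus strand). All 4 are protein-coding, and each value counts the whole gene. Dnmt3a was at 75.1 FPKM in siControl and 59.8 in the siDnmt3a library, a difference of -20.3%, and 0.4% of the 500 genes nearest in expression were lower by more. It was at 77.6 in the siDnmt3b library and at 69.5, or -7.45%, in the double siRNA library, where 11.8% of such genes were lower by more. Dnmt3b was at 146.3 FPKM in siControl and 128.3 in the siDnmt3b library, a difference of -12.3%, with 0.6% of comparable genes lower by more. It was at 134.8 in the siDnmt3a library (-7.91%) and 135.0 in the double siRNA library (-7.73%), where 2.6% and 9.2% of comparable genes were lower by more. Each target was thus lowest in the library of its own single siRNA, and neither stood apart from comparable genes in the double siRNA library. Dnmt1 lay between 78.5 and 79.6 FPKM and Dnmt3l between 52.7 and 62.5 over the 4 libraries.

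**Figure D1:**
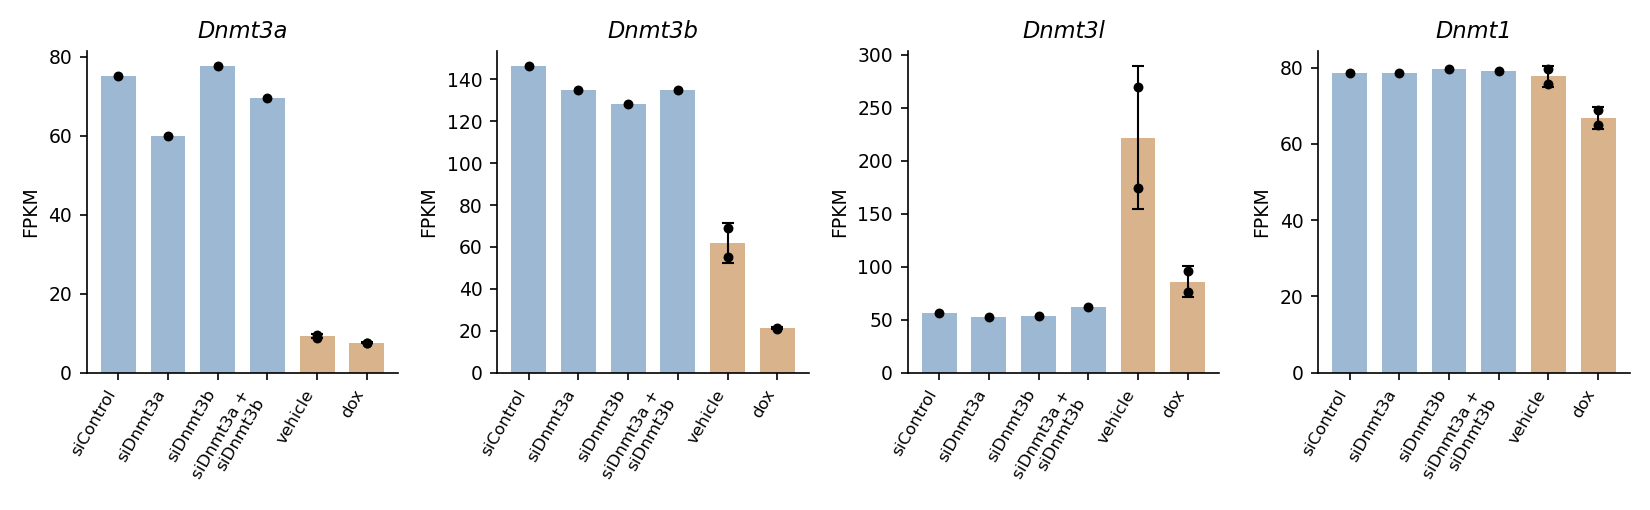
FPKM of Dnmt3a, Dnmt3b, Dnmt3l and Dnmt1 per group, with bars for the mean, points for single libraries and error bars for the SD of 2 clones. Dnmt3a was at 59.8 to 77.6 FPKM in the 4 wild-type libraries, and Dnmt3b was at 21.2 in dox against 62.0 in vehicle.

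Few genes differed from siControl by 2-fold. There were 8 higher and 10 lower in the siDnmt3a library of 11768 genes, 6 higher and 7 lower in the siDnmt3b library of 11727, and 12 higher and 16 lower in the double siRNA library of 11723. Clones 1 and 2 differed from each other by 2-fold at 39 genes within the dox group and at 24 within the vehicle group, the only replicate pairs in the series. The SD of all log2 differences was 0.159, 0.134 and 0.246 for siDnmt3a, siDnmt3b and the double siRNA, against 0.208 and 0.199 between the clones. The siRNA comparisons share the siControl library, and a chance value of that library enters all 3.

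Among the genes lower in all 3 libraries, Dcn, a collagen-binding proteoglycan, was at 8.27 FPKM in siControl and at 3.65, 3.63 and 3.13 in the siDnmt3a, siDnmt3b and double siRNA libraries. The fibrillar collagen gene Col3a1 was at 30.3 against 15.4, 15.8 and 12.7, and Col1a1 at 36.1 against 20.96, 18.6 and 18.2. Mmp3, a matrix-degrading protease, was at 17.5 against 8.36, 9.94 and 7.24. H19, an imprinted long non-coding RNA, differed by -0.80, -1.03 and -1.19 (log2), and Igf2, its imprinted neighbour that encodes a growth factor, by -0.57, -0.56 and -0.62. Akr1b3, which encodes aldose reductase, differed by -0.79, -1.27 and -1.36. These genes moved with the list of feeder fibroblast markers, whose median differed by -0.54, -0.52 and -0.68, with 34 of 35, 34 of 34 and 33 of 35 members lower. All 3 medians lay below every one of 10000 matched random lists (percentile 0).

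On the higher side, Sap25, which encodes a protein of the Sin3A corepressor complex, was at 1.15 FPKM in siControl and at 3.87, 4.89 and 5.67 in the siDnmt3a, siDnmt3b and double siRNA libraries. Insl3, a peptide hormone gene, was at 0.693 against 2.48, 2.201 and 2.62. Rpph1, the RNA of ribonuclease P, was at 16.0 against 34.2, 21.5 and 37.1, and Hbb-bh1, an embryonic globin gene, at 5.36 against 9.78, 6.11 and 13.7. Rpl41, a ribosomal protein gene, was higher by 0.84 (log2) in the double siRNA library. The double siRNA differences followed GC content and transcript length across genes (Spearman's rho 0.485 and -0.481), and the values given here are not corrected for these.

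The largest differences were of genes that share sequence with a copy, and they are uncertain. Amd2, which encodes an enzyme of polyamine synthesis, was at 58.5 FPKM in siControl, 2.06 with siDnmt3a and 1.40 with the double siRNA, while its copy Amd1 was at 13.96, 62.4 and 55.5. Btg3, an antiproliferative gene, was at 0.0153, 10.8 and 23.9 in the same libraries. Eif3j, which encodes a subunit of a translation initiation factor, was at 10.995, 0.00346 and 0.00321.

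Besides the fibroblast markers, most list medians lay within 0.1 (log2) of siControl. The random lists were matched on expression and not on GC content or transcript length, which the double siRNA differences followed across genes (Spearman's rho 0.485 and -0.481). Imprinted genes, with H19 and Igf2 among them, had medians of -0.05, -0.07 and -0.11 for siDnmt3a, siDnmt3b and the double siRNA (percentiles 1.1, 0.01 and 0.15 among random lists), and 24, 23 and 22 of 32 members were lower. Germline genes that DNA methylation silences had medians of 0.04, 0.06 and 0.14 (percentiles 91.3, 99.3 and 99.9), with 11 of 19, 13 of 18 and 10 of 16 members higher. Among them, Mael, a piRNA pathway gene, was at 2.84 FPKM in siControl and 3.64, 3.21 and 3.62 in the siRNA libraries, while Sycp1, a meiotic gene, differed by -0.26, 0.02 and -0.64 (log2). Genes of the 2-cell-like state had medians of 0.23, 0.22 and 0.03 (percentiles 99.94, 99.99 and 82.3). Only 9, 8 and 7 of 34 were measured, of which 6, 7 and 5 were higher. The embryonic gene Zscan4c of this list was at 0.964, 1.42, 1.505 and 0.925 FPKM in siControl and these libraries. In the double siRNA comparison its mean lay under 1 FPKM, so that median leaves it out. Reads shared among the Zscan4 genes of the list were not tested, so these values are uncertain.

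Interferon response genes had medians of -0.16, -0.11 and -0.02 (percentiles 0, 0 and 35.4). Ifi44 differed by -0.70, -0.60 and -0.72, and Isg15, a ubiquitin-like modifier, by -0.17, -0.11 and 0.48. Naive and core pluripotency genes had medians of -0.07, -0.04 and 0.05 (percentiles 0, 0.11 and 20.2). Pou5f1, the core factor Oct4, was at 888 FPKM in siControl and 915, 922 and 1224 in the siRNA libraries. Tfcp2l1, a factor of the naive state, differed by -0.20, -0.16 and -0.30. Genes of the DNA methylation machinery had medians of -0.06, -0.05 and -0.01 (percentiles 0.14, 0.04 and 8.69), and Hells, a chromatin remodeller needed for DNA methylation, differed by -0.15, 0.16 and -0.56. Published miR-203 targets had medians of -0.07, -0.02 and -0.07 (percentiles 0.38, 10.96 and 3.79), with Cav1, a gene of membrane caveolae, at -0.83, -0.39 and -0.67.

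Lineage markers were low or mixed. The 4 measured mesoderm and primitive streak genes had medians of -0.38, -0.24 and -0.05 (percentiles 0.07, 0.95 and 59.3), with Bmp4, a signalling ligand, at 5.00 FPKM in siControl and 2.85, 3.16 and 4.83 in the siRNA libraries. Endoderm genes had medians of -0.07, -0.14 and -0.03 (percentiles 2.86, 0.02 and 35.5), led by the basement membrane collagen Col4a2 at -0.23, -0.41 and -0.32 and the matrix protein gene Sparc at -0.24, -0.39 and -0.18. Trophoblast medians were 0.06, -0.15 and -0.02 (percentiles 92.1, 0.78 and 63.6), and neuroectoderm medians 0.05, 0.02 and -0.05 (percentiles 94.8, 86.0 and 25.4). Primed pluripotency medians were -0.01, -0.01 and 0.14 (percentiles 40.7, 28.5 and 96.1), and Hox medians 0.00, -0.08 and -0.07 (percentiles 70.5, 2.54 and 33.9). Medians of the p53 response were -0.01, -0.02 and -0.07 (percentiles 37.7, 18.8 and 5.40), those of proliferation -0.00, 0.01 and 0.05 (percentiles 11.1, 33.5 and 1.98), and those of immediate early and heat shock genes -0.02, -0.00 and 0.14 (percentiles 13.3, 29.8 and 96.2).

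Across 12042 genes, the siDnmt3a and siDnmt3b differences correlated at r = 0.510 and those of siDnmt3a and the double siRNA at r = 0.603. Unchanged libraries with the same shared control, simulated over 11657 genes, gave 0.5, a value set in advance by equal spread in all libraries. The siDnmt3b and double siRNA differences correlated at r = 0.316. The covariances were 0.0110, 0.0236 and 0.0105 in that order, beside a simulated 0.0136. The simulated spread came from the knock-in libraries and may differ from that of the wild-type ones, so no excess or shortfall is read from it. With 1 control library the controls could not be split, and part of any excess can come from sharing it.

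In the knock-in line, the dox and vehicle libraries were compared 2 weeks after withdrawal. Dnmt3b was at 21.2 ± 0.487 FPKM in dox against 62.0 ± 9.71 in vehicle (mean ± SD, n = 2 each), and fell by 1.498 on the log2 scale (SE 0.114, limma adjusted p = 5.28e-04). Dnmt3l was at 86.0 ± 14.5 against 222 ± 67.6, and fell by 1.33 (SE 0.209, limma adjusted p = 0.00629). Dnmt3a was at 7.60 ± 0.0613 against 9.20 ± 0.496, a difference of -0.25 that did not pass (SE 0.0904, limma adjusted p = 0.0796), and it passed with the clone as a block (adjusted p = 0.0304). Dnmt1 was at 66.9 ± 2.89 against 77.7 ± 2.73, or -0.21 (SE 0.0746, limma adjusted p = 0.0710, and 0.0102 with the block).

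In the list of DNA methylation machinery, 8 of 21 measured genes fell, none rose and 13 did not pass, and adjusted over the list alone 10 fell and 2 rose. The fibroblast markers rose in the same libraries by a median of 1.59. Hells was at 52.8 FPKM in dox against 93.7 in vehicle (-0.82, limma adjusted p = 0.00250). Trim28, which encodes a corepressor recruited by zinc finger proteins, was at 378 against 631 (-0.74, limma adjusted p = 0.00266). Of the list, adjusted over all genes, 4 fell without vehicle clone 1, and 1 rose without dox clone 1. The median was -0.20 (camera adjusted p = 0.00262), and the call was lost at adjusted p = 0.526 with an estimated correlation.

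At this threshold, 2035 of 11927 genes rose and 1767 fell in dox, 356 and 115 of them by 2-fold or more. With the clone as a block, 3052 rose and 3190 fell. Without dox clone 2, 1316 rose and 940 fell. Without vehicle clone 1, these were 1100 and 538, and without vehicle clone 2, 1642 and 1057. Lcn2, a secreted iron-scavenging protein gene on chromosome 2 from 32384633 to 32388252, had the largest rise of the genes named under the rule. It rose from 11.5 ± 0.522 FPKM in vehicle to 161 ± 7.24 in dox (n = 2 each), by 3.69 on the log2 scale (SE 0.0787, limma adjusted p = 2.26e-05). Mmp3, on chromosome 9 from 7445822 to 7455975, rose from 23.8 ± 2.13 to 283 ± 29.5 FPKM. H19, on chromosome 7 from 142575529 to 142578143, rose from 5.47 ± 2.02 to 54.8 ± 0.996. The chemokine genes Ccl22 and Cxcl5 rose from 5.01 to 52.2 and from 6.16 to 59.7 FPKM, and the serum amyloid gene Saa3 from 416 to 2358. Sod3, an extracellular superoxide dismutase gene, rose by 2.45, and P4ha2, which encodes a collagen hydroxylase, by 2.40 (limma adjusted p = 1.42e-04 and 6.46e-05).

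**Figure D2:**
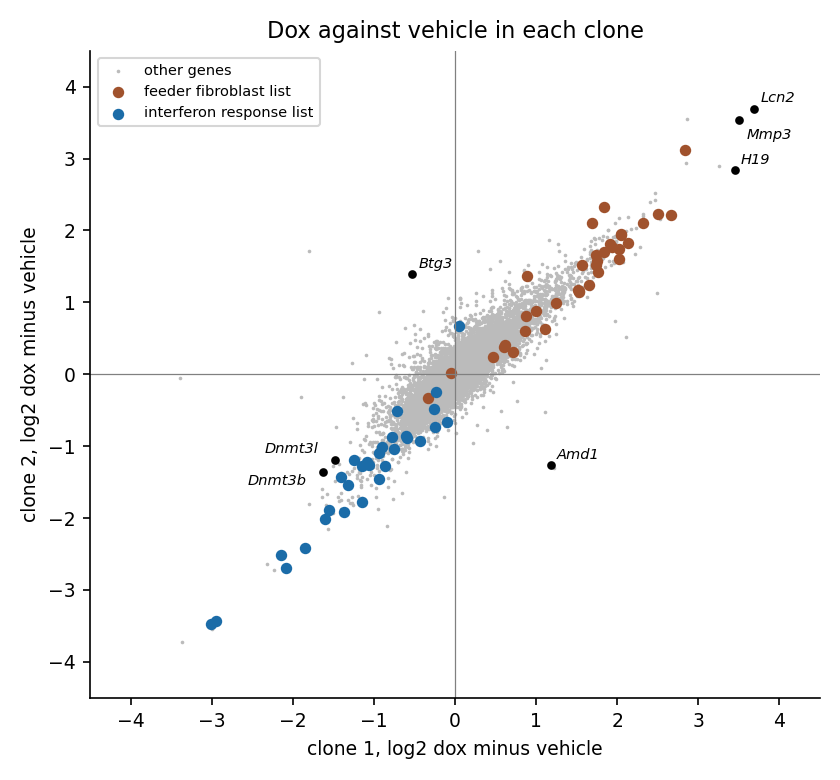
Log2 difference of dox minus vehicle in clone 1 (x axis) and clone 2 (y axis), with 1 point per tested gene and colours for the feeder fibroblast and interferon response lists, and 1 gene lying beyond the plotted range. Lcn2 lies at 3.69 and 3.69, and Amd1 and Btg3 have opposite signs in the clones.

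Markers of feeder fibroblasts rose as a group. Of 35 measured, 32 rose, Tagln fell and 2 did not pass, and adjusted over the list alone the counts were 32 and 1. None fell without vehicle clone 1 or vehicle clone 2. Dcn rose from 17.7 ± 1.69 FPKM in vehicle to 147 ± 7.12 in dox (2.98, SE 0.0908, limma adjusted p = 5.67e-05). Col1a1 rose from 109 to 505, Col1a2 from 67.4 to 350 and Col3a1 from 32.4 to 179. Tagln, an actin-binding gene of contractile cells named here after its value was seen, fell by 0.33 (limma adjusted p = 0.0226), and Acta2, smooth muscle actin, also named after its value was seen, was at 31.8 against 32.2. The list median was 1.59 (camera adjusted p = 2.57e-20). The call was lost at adjusted p = 0.526 with an estimated correlation, a test with few residual degrees of freedom here.

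The endoderm and Hox lists were called higher in the libraries where the fibroblast markers rose by a median of 1.59. Of 14 endoderm genes, 7 rose, Podxl, a sialomucin gene, fell and 6 did not pass, with the same counts of 7 and 1 adjusted over the list alone (median 0.42, camera adjusted p = 0.00104, and p = 0.526 with an estimated correlation). The members with the largest rises were matrix genes and Dab2, an endocytic adaptor. Col4a2 rose by 1.25 and Lamb1, a laminin chain, by 1.25, and Sparc rose from 255 to 598 FPKM. Of 8 Hox genes, 5 rose and 3 did not pass, and adjusted over the list alone 7 rose (median 0.69, camera adjusted p = 0.00102, and p = 0.526 with an estimated correlation). The estimated correlation of the Hox list was -0.00236, below the preset 0.01, so correlation between genes did not cost this call. Hoxb9, a gene of the trunk axis, rose from 1.29 to 3.57 FPKM.

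Interferon response genes fell as a group. Of 30 measured, 28 fell and 2 did not pass, and adjusted over the list alone 29 fell and 1 rose. Without dox clone 1 or vehicle clone 1, 1 rose. Cmpk2, an interferon-induced nucleotide kinase gene on chromosome 12 from 26469204 to 26479837, had the largest fall of the named genes, from 60.2 ± 9.21 FPKM in vehicle to 5.33 ± 0.750 in dox (-3.27, SE 0.134, limma adjusted p = 1.17e-04). Ifit2, which encodes an antiviral RNA-binding protein, went from 157 ± 21.6 to 15.7 ± 1.48 (-3.24), Rsad2, which encodes viperin, from 118 to 11.9 (-3.19), and the chemokine gene Cxcl10 from 270 to 51.0 (-2.39). Ifnb1, which encodes interferon beta itself, went from 5.34 ± 0.745 to 0.138 ± 0.0425 (-2.47, limma adjusted p = 1.93e-04). The list median was -1.16 (camera adjusted p = 8.76e-18), and the call was lost at adjusted p = 0.526 with an estimated correlation. The fibroblast markers rose in the same libraries.

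Of 28 proliferation genes, 17 fell and 11 did not pass, and adjusted over the list alone 21 fell. Adjusted over all genes, the count was 3 without vehicle clone 1, 7 without dox clone 2 and 9 without vehicle clone 2. Ccne1, the G1/S cyclin E1, fell from 67.9 to 44.7 FPKM (-0.59), and Aurka, a mitotic kinase gene, by 0.43. The median was -0.29 (camera adjusted p = 4.50e-07, and p = 0.526 with an estimated correlation). Of 17 germline genes, Hormad1, Sycp1, Rpl10l and Tex19.1 fell and 13 did not pass, also adjusted over the list alone. Their differences were -0.72, -0.65, -0.64 and -0.54, and the list median was -0.29 (camera adjusted p = 0.00380). The germline call was lost at adjusted p = 0.589 with an estimated correlation, at 0.0831 with the correction for GC content and length, at 0.0908 with a minimum of 5 FPKM, and at 0.0672 without dox clone 1. Without vehicle clone 1, Hormad1 and Rpl10l did not pass (adjusted p = 0.0629 and 0.0877). Fibroblast markers rose by a median of 1.59 in the same comparison.

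The pluripotency lists moved both ways and were not called. Of 26 naive and core genes, 6 rose, 7 fell and 13 did not pass, and adjusted over the list alone 6 rose and 10 fell (median -0.08, camera adjusted p = 0.496), and 4 fell without vehicle clone 1. Klf4, a reprogramming factor, rose from 65.3 to 113 FPKM (0.79, limma adjusted p = 0.00306), and Tbx3 rose by 0.63 and Dppa5a, an RNA-binding marker of pluripotent cells, by 0.83. Zfp296 fell from 28.0 to 13.4 FPKM (-1.01), and Dppa2 and Dppa4, partner activators of early embryonic genes, fell by 0.88 and 0.63. Of 15 primed pluripotency genes, 2 rose, 6 fell and 7 did not pass, and adjusted over the list alone 3 rose and 6 fell (median -0.28, camera adjusted p = 0.226). Leaving out vehicle clone 1 or vehicle clone 2 left 1 and 0 that rose. Pou3f1, the primed-state factor Oct6, fell from 4.16 to 0.675 FPKM (-1.62, limma adjusted p = 3.72e-04), and Etv4, a target factor of FGF signalling, fell by 1.22. The Nodal antagonist Lefty1 rose from 4.75 ± 2.86 to 20.9 ± 15.4 FPKM (n = 2 each, 1.82, limma adjusted p = 0.0429). Without vehicle clone 2 its difference was 1.29 and did not pass. Lefty2 was higher by 1.81 without passing (limma adjusted p = 0.0589, and 1.09e-04 with the clone as a block). Its difference depended on the dox clone, at 0.80 without dox clone 1 and 2.81 without dox clone 2.

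Imprinted genes moved in both directions. Of 29 measured, 10 rose, 10 fell and 9 did not pass, and adjusted over the list alone 10 rose and 11 fell. Adjusted over all genes, 7 of them rose and 4 fell without vehicle clone 1. The median was -0.07 and the mean 0.10, and the list was not called (camera adjusted p = 0.939). Beside H19, Igf2 rose from 8.58 to 33.6 FPKM (1.86, limma adjusted p = 1.82e-04). Peg10, a retrotransposon-derived placental gene, fell from 9.15 to 3.00 (-1.35, limma adjusted p = 0.00211), and Nnat, a membrane proteolipid gene of neurons, fell by 0.99. Igf2 and H19 were lower in the siRNA libraries and higher in dox together with the fibroblast markers.

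**Figure D3:**
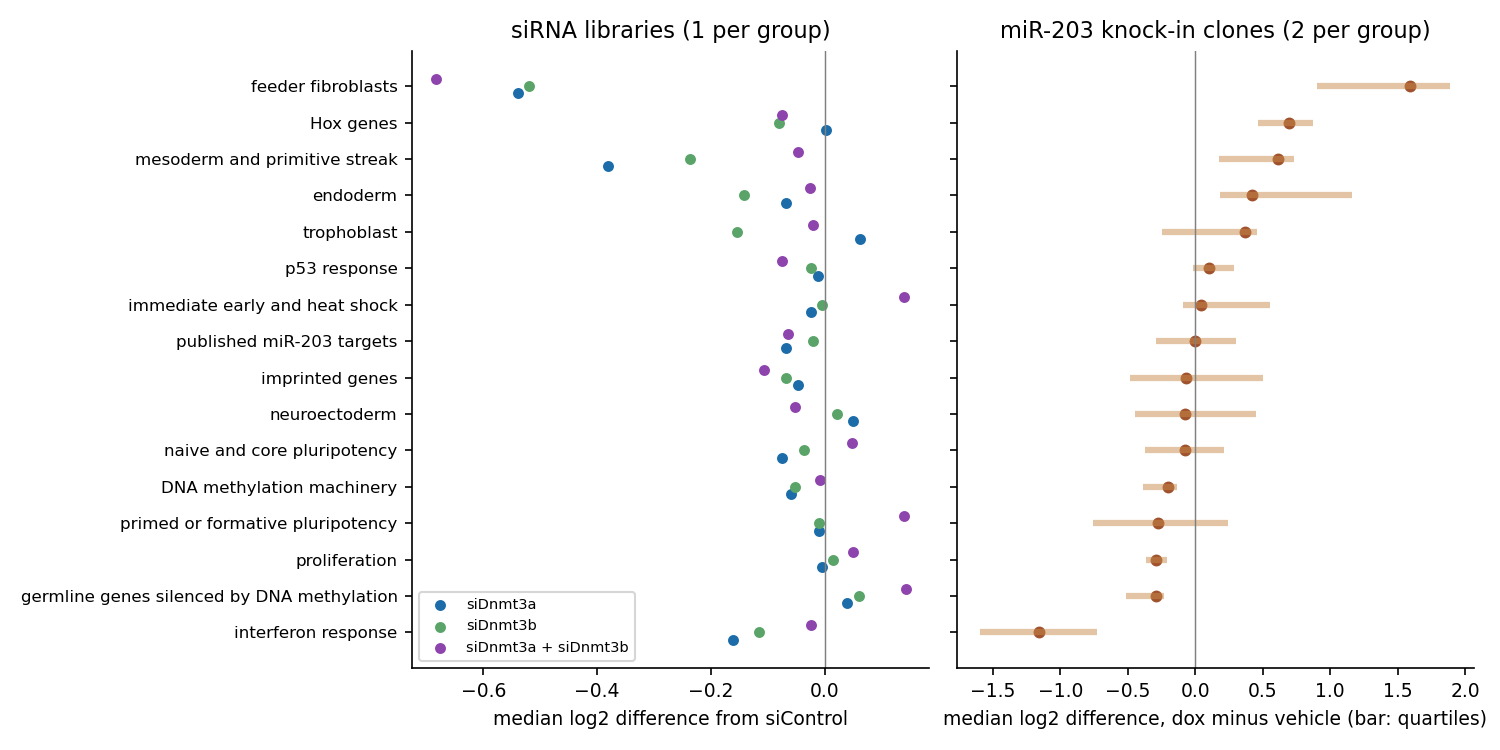
Median log2 difference of each gene list in the 3 siRNA libraries against siControl (left, 1 library each) and in dox against vehicle (right, n = 2 per group, bars for quartiles). The fibroblast median lay at -0.54, -0.52 and -0.68 in the siRNA libraries and at 1.59 in dox, and the interferon median at -1.16 in dox.

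The other lists were not called with camera. Of 4 mesoderm genes, Cdx1, Snai1 and Eomes rose and Bmp4 fell, also adjusted over the list alone (median 0.62, camera adjusted p = 0.148). Of 11 neuroectoderm genes, 3 rose and 4 fell, also adjusted over the list alone, among them Sox11, which fell by 0.95, and En1, which rose by 0.84 (camera adjusted p = 0.939), and the median of -0.08 and the test lay on the lower side while the mean was 0.02. Of 10 trophoblast genes, 5 rose and none fell, and adjusted over the list alone 6 rose and 1 fell (median 0.37, camera adjusted p = 0.147), with the keratin gene Krt8 rising from 8.15 to 15.5 FPKM. Of 20 genes of the p53 response, 5 rose and Eda2r fell, and adjusted over the list alone 5 rose and 0 fell (median 0.10, camera adjusted p = 0.179), with Plk2, a stress-responsive kinase gene, rising by 0.88. The p53 list was called without dox clone 1 (adjusted p = 0.0296, and 0.646 with an estimated correlation) and the trophoblast list without vehicle clone 2 (adjusted p = 0.0402, and 0.727 with an estimated correlation), Eomes was lost without vehicle clone 1 (adjusted p = 0.0573), and Eda2r (adjusted p = 0.0497) was lost without vehicle clone 1, dox clone 1 or dox clone 2 (adjusted p = 0.262, 0.108 and 0.0769). Without vehicle clone 2, 2 neuroectoderm genes fell and 3 p53 genes rose. Of the trophoblast genes, 3 rose and 3 fell without dox clone 2, 3 rose and 1 fell without vehicle clone 1, and 3 rose without vehicle clone 2. Of 18 immediate early and heat shock genes, 5 rose and 3 fell, and adjusted over the list alone 6 rose and 3 fell (median 0.04, camera adjusted p = 0.264), with Ier3, a stress-induced survival gene, rising from 25.02 to 58.9 FPKM, and 1, 0 and 1 fell without dox clone 2, vehicle clone 1 and vehicle clone 2. Of the 2-cell-like list, Sp110, a nuclear body gene, was the 1 member measured and fell from 7.87 to 3.62 FPKM (-0.94, limma adjusted p = 0.00212). With no filter on low values 28 members were measured, 1 of which fell, and the list was called lower (camera adjusted p = 0.0375, and 0.396 with an estimated correlation). The fry test, which asks whether a list moves 1 way on balance, called the fibroblast, interferon, Hox and mesoderm lists (adjusted p = 0.0221 each). These calls were lost with the clone as a block (adjusted p = 0.0896 to 0.110) and without any 1 of the 4 libraries. That of the mesoderm list was also lost with the correction for GC content and length (0.0544). The block and a library left out both leave fewer residual degrees of freedom, which alone can cost a fry call. The losses therefore do not show that the calls rest on the clone or on any 1 library.

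Targets of miR-203 were examined as published genes and as seed matches. Of 18 published targets, 5 rose, 3 fell and 10 did not pass, and adjusted over the list alone 5 rose and 4 fell. Without dox clone 1, 5 fell, without vehicle clone 1, 3 rose and 1 fell, and without dox clone 2 or vehicle clone 2, 3 rose. The median was -0.00, the mean was 0.04 and the list was not called (camera adjusted p = 0.805). Dnmt3b fell as above, while Cav1 and Snai2, an epithelial-mesenchymal transition factor, rose by 0.97 and 0.81 together with the fibroblast markers. Of 11450 genes with a 3' UTR, 2030 had a match to the 7-base seed, and their mean difference was lower than that of the rest by 0.029. As low or lower a value was seen for 146 of the 210 sequences of the same base composition, the seed match among them. Camera called neither this set nor the 598 genes with the longer match of 8 bases.

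The series was designed to set the transcriptomes after Dnmt3a and Dnmt3b silencing beside those after transient miR-203. In the siRNA libraries, however, the targets were not far below siControl. Dnmt3a was at -20.3% with siDnmt3a, Dnmt3b at -12.3% with siDnmt3b, and they were at -7.45% and -7.73% with the double siRNA. Dnmt3a was also at 7.55 to 9.55 FPKM in the knock-in libraries, against 59.8 to 77.6 in the wild-type ones. The values below therefore do not show whether a strong loss of either gene would resemble the dox differences. Over 12042 genes, the dox differences of clones 1 and 2 correlated at r = 0.887, and 280 genes were 2-fold higher and 77 were 2-fold lower in both. The siDnmt3a, siDnmt3b and double siRNA differences correlated with the mean of the clones at r = -0.059, -0.285 and -0.059 (Spearman's rho 0.085, -0.226 and -0.007), across genes, which are not independent replicates. With the correction for GC content and length, r was -0.096, -0.251 and -0.188. The 280 genes higher in dox had median siRNA differences of -0.19, -0.22 and -0.21, all at percentile 0 of matched random lists. Of these, 77.5%, 87.5% and 81.4% were lower than in siControl, against 52.4%, 51.8% and 49.7% of all genes. The fibroblast marker list was lower in the same siRNA libraries, by medians of -0.54, -0.52 and -0.68. The 77 genes lower in dox had medians of -0.10, -0.06 and -0.01, at percentiles 0, 0 and 51.1.

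No gene was 2-fold higher both in an siRNA library and in both dox clones, where 0.19, 0.09 and 0.23 were expected from independent lists. Of genes 2-fold lower in both, there were 0, 0 and 1 against 0.07, 0.06 and 0.10 expected. Genes lower with siRNA and higher in dox numbered 2, 3 and 7, against 0.26, 0.21 and 0.35. Of the named genes, Lrrc17, which encodes a secreted leucine-rich protein, had the largest increase shared by the double siRNA library and both clones. It was higher by 1.03 in the double siRNA library and by 0.80 and 0.78 in the clones. Zfp534, a zinc finger gene, differed by -0.88 in the double siRNA library and by -1.51 and -1.94 in the clones, and Xpo1, the nuclear export receptor gene, by -0.68, -0.67 and -0.86. Tested in the dox comparison, the 15 measured genes 2-fold lower in the double siRNA library were higher as a set (8 rose, 3 fell, camera adjusted p = 0.0484), as were the 7 lower with siDnmt3b (4 rose, camera adjusted p = 0.0484). Fibroblast markers, whose list rose by a median of 1.59, made up 3 and 1 of the genes 2-fold lower in these siRNA libraries. The double siRNA set also held Amd2 and Eif3j, whose siRNA values are uncertain. Without small RNA, predicted, clone and pseudogene names, 11 of 16 genes 2-fold lower with the double siRNA and 4 of 7 with siDnmt3b remained. Both calls were lost at adjusted p = 0.403 with an estimated correlation at 0.148 with the clone as a block, at 0.0543 with the block and the correction for GC content and length, and at 0.129 with no filter. Those of the double siRNA and siDnmt3b sets were lost at 0.0586 and 0.0694 with a pseudocount of 0.1 and at 0.0533 and 0.0550 with 0.5, that of the double siRNA set at 0.181 without dox clone 1, where 6 fell, and that of the siDnmt3b set at 0.0513 with quantile scaling. Without vehicle clone 2, 2 of the siDnmt3b set fell. Fry called the sets lower with siDnmt3a, siDnmt3b and the double siRNA (adjusted p = 0.00483, 0.00190 and 0.00483). These calls were lost with the clone as a block (0.311, 0.130 and 0.130) and with 1 library left out, except that of the double siRNA set without dox clone 2. Both settings leave fewer residual degrees of freedom, which alone can cost a fry call. The sets lower and higher with siDnmt3a (adjusted p = 0.528 each), whose medians had the opposite sign to their tests, and the set higher with the double siRNA (adjusted p = 0.315) were not called with camera.

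**Figure D4:**
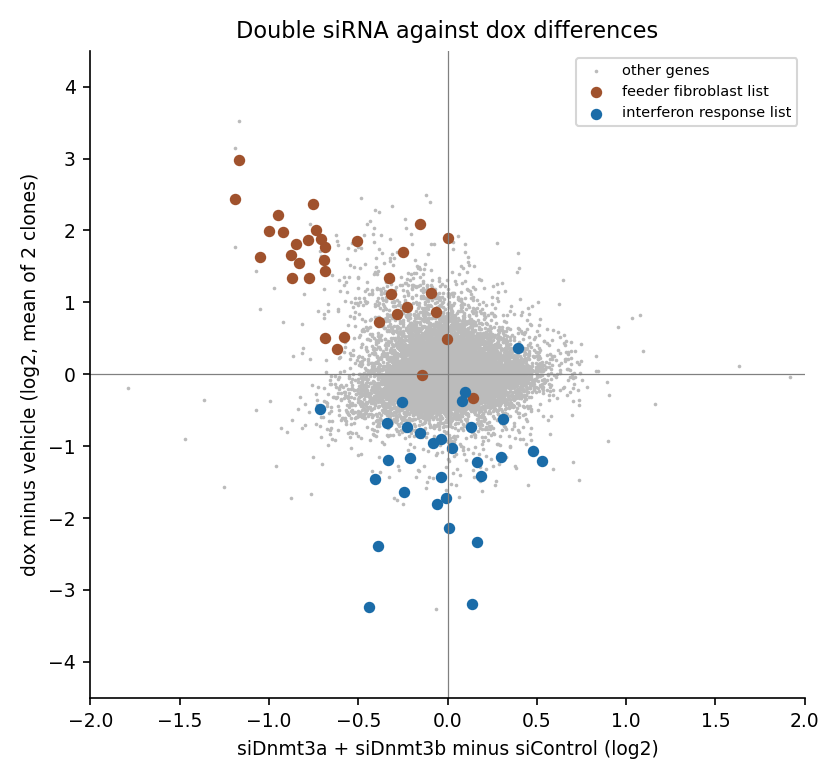
Log2 difference of the double siRNA library against siControl (x axis) and of dox against vehicle (y axis, mean of 2 clones) for each gene, with 3 genes lying beyond the plotted range. The fibroblast list lies at lower siRNA and higher dox values, and the correlation over all genes was -0.059, or -0.188 with the correction for GC content and length.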

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

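The tests of reads shared by Amd2 and by Btg3 with a copy were chosen after the result was seen, and those of Eif3j and Gm15772 before it was. Amd1 and Btg3 had dox differences of opposite sign in clones 1 and 2. The log2 difference of Amd1 was 1.18 in clone 1 and -1.27 in clone 2, and that of Btg3 was -0.53 and 1.39. The difference between the clones was not tested in either gene, since each clone has 1 library per condition. Amd1 was at 12.2 FPKM in vehicle and 28.9 in dox in clone 1, and at 56.8 and 23.0 in clone 2, where its copy Amd2 was at 34.9 and 27.9. The sums of Amd1 and of Btg3 with a copy were tested only in the siRNA libraries. Division of reads in clone 1, and for Btg3 in either clone, therefore stays open.

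Amd2, Eif3j and Btg3 were near 0 in some siRNA libraries and not in others, and Gm15772, a predicted gene named after its values were seen, was at 0.220 FPKM or less in vehicle and at 186 to 415 in dox. Reads shared with the partner gene that had the most 30-base words in common were tested for each. Eif3j shared 41.1% of these words with Gm9781, and Gm15772 shared 85.3% with Rpl26. For Amd2, which shares 91.2% of its 30-base words with Amd1, the summed FPKM of the pair moved by -0.34 (log2) or less in size in the siDnmt3a and double siRNA libraries, while Amd2 alone moved by -4.28 and -4.63, and for Btg3, which shares 13.8% with Gm7334, the sum moved by -0.07 or less in size. Division of shared reads is a candidate explanation for these pairs in the siRNA libraries, though for Btg3 it rests on a small shared part. In clone 2, Amd1 and Amd2 were both lower in dox, which goes against a plain exchange between them there. For Eif3j (sum -0.34) and Gm15772 (sum 0.21), division of reads cannot be told apart from a change of the gene itself. Their copies lay above them, and a small change of the copy would hide the exchange. The copy of Eif3j, Gm9781, was at 51.7 FPKM in siControl, 55.9 with siDnmt3a and 49.4 with the double siRNA, where it was lower together with Eif3j. That of Gm15772, Rpl26, was at 1669 in vehicle and 1438 in dox in clone 1, and at 1579 and 1646 in clone 2, where it was higher together with Gm15772. The values with the double siRNA and in clone 2 go against a plain exchange of reads. An effect of the siRNAs, dox or miR-203 on these genes stays open and was not tested apart from the copies.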

How the results depend on the processing

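The correction for GC content and length, alone or with the clone block, and the siRNA counts without small RNA, predicted, clone and pseudogene names were chosen after the data were seen. Among the main values of the comparisons, 158 alternative values stayed within 1.5 times a count or within the spread of a value, 80 moved beyond it, and no called value changed sign. The 158 include the siRNA correlations with dox at the 1.5-fold limit, which use no fold limit and could not move. For 123 named genes in dox, 1579 of 1688 alternative values kept direction and side of the threshold, 91 no longer passed, 18 newly passed and 0 turned sign. A robust variance fit and median-ratio scaling moved none of the main values. The groups have 2 clones or 1 siRNA library each, and depth in fragments is unknown. Except where fewer genes, fewer libraries or another threshold make the count, the cause was not tested.

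With the clone as a replicate block, all 3802 calls of the fit without it were shared, and genes lower in dox numbered 3190 in place of 1767, or 3385 with the block and the GC and length correction, where 2520 were higher. The block changed the calls of Dnmt1, Dnmt3a, Lefty2, Rhox6 and Mgp, of the siDnmt3b and double siRNA sets, and of Akr1b3, Amd2, Pou5f1 and Rpph1, named in the report for siRNA values, and no other camera call of a list or call of a gene named in the report. With the block, which leaves fewer residual degrees of freedom, fry lost its 4 list calls. It called the DNA methylation and endoderm lists in their place (adjusted p = 0.0228 and 0.0348). It also called the DNA methylation, endoderm, proliferation, 2-cell-like and miR-203 target lists with no filter (0.0419 each), proliferation with quantile scaling (0.0446), miR-203 targets without dox clone 2 (0.0231), the 7-base seed set as higher with the GC and length correction (0.0324, and 0.00502 with the block), and with block and correction together the DNA methylation, proliferation and naive and core lists (0.0414, 0.0414 and 0.0448), and the genes higher with siDnmt3a as lower with pseudocounts of 0.1 and 0.5, no filter and quantile scaling (0.0241, 0.0378, 0.0328 and 0.0407). Leaving out 1 library gave 1100 to 2064 genes higher in dox against 2035, and 538 to 1993 lower against 1767, where the lone library left in a group is assumed to vary like the other group. With a minimum of 5 FPKM, 1289 genes were higher and 226 of them by 2-fold, and with no filter 947 were lower. A pseudocount of 0.1 gave 602 higher and 188 lower by 2-fold. Of 7 lists called with camera, 0 were called with an estimated correlation and 3 with fry, which called the mesoderm list as well. With so few residual degrees of freedom, the loss of all 7 does not show that correlation between genes made these calls.

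Counts of genes at 2-fold were 18, 13 and 28 for siDnmt3a, siDnmt3b and the double siRNA, 39 between dox clones and 24 between vehicle clones. In that order they were 93, 78, 233, 167 and 142 at 1.5-fold, 6, 3, 6, 9 and 9 at 3-fold, 45, 31, 70, 87 and 56 with a pseudocount of 0.1, and 7, 5, 15, 17 and 9 with a minimum of 5 FPKM. The double siRNA count was 44 with a pseudocount of 0.5, and the siDnmt3b count 21 with no filter. Without small RNA, predicted, clone and pseudogene names the siRNA counts were 9, 6 and 18.

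The correlation of siDnmt3b with dox (-0.285) was -0.252 with a pseudocount of 0.1, -0.236 with no filter, -0.323 with a minimum of 5 FPKM, -0.269 with quantile scaling, -0.251 with the GC and length correction, -0.27 with clone 2 alone and -0.269 without the fibroblast, interferon and immediate early lists. With the GC and length correction, those of siDnmt3a and the double siRNA were -0.096 and -0.188 against -0.059 each. The medians of genes higher in dox were -0.191, -0.219 and -0.215 for siDnmt3a, siDnmt3b and the double siRNA. That of siDnmt3a was -0.18 with no filter, -0.212 with a minimum of 5 FPKM, -0.091 at 1.5-fold, -0.174 and -0.138 with clone 1 or 2 alone, and -0.166 without the 3 lists. That of siDnmt3b was -0.245 and -0.233 with pseudocounts of 0.1 and 0.5, -0.236 at 5 FPKM, -0.209 with quantile scaling, -0.132 at 1.5-fold, -0.206 and -0.183 with clone 1 or 2 alone, and -0.199 without the lists. That of the double siRNA was -0.259 and -0.252 with the pseudocounts, -0.25 at 5 FPKM, -0.185 with quantile scaling, -0.24 with the GC and length correction, -0.118 at 1.5-fold, -0.154 with clone 2 alone and -0.197 without the lists. The medians of genes lower in dox were -0.095, -0.062 and -0.006. For siDnmt3a this was -0.112 at 5 FPKM, -0.078 with quantile scaling and -0.071 at 1.5-fold. For siDnmt3b it was -0.079, -0.043 and -0.009 under the same settings, -0.046 with the GC and length correction, -0.03 with clone 2 alone and -0.041 without the lists, and for the double siRNA 0.027 with quantile scaling.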

Other observations

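The tests of feeder RNA, of an unchanged feeder profile and of the share of pluripotent cells were chosen after the result was seen, as were the macrophage markers and the genes named in the next paragraphs, while the correction of the double siRNA spread was chosen before its value was seen.

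The wild-type and knock-in lines differed in some pluripotency genes. Of 12042 genes, 86 were at least 4-fold higher in all 4 wild-type libraries than in any knock-in library, and 92 were at least 4-fold higher in all 4 knock-in libraries. The first group held 6 of 19 primed pluripotency, 5 of 39 imprinted and 8 of 39 Hox genes. Pou3f1 lay at 33.1 to 38.2 FPKM in wild-type and 0.621 to 4.17 in knock-in libraries, Dnmt3a at 59.8 to 77.6 against 7.55 to 9.55, and the imprinted gene Nnat at 82.2 to 89.99 against 1.93 to 5.77. The naive factor Tfcp2l1 lay at 6.30 to 7.98 against 70.2 to 110.0, while Pou5f1 overlapped between the lines at 888 to 1224 and 855 to 1048. The embryonic gene Tcstv3 was at 1.12 to 1.33 FPKM in wild-type libraries and listed at 0 in all knock-in libraries. The lines differ in genotype, clone and treatment together, so these are values of 2 sets of libraries and no test was made.

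Of 30 interferon response genes 7, and of 36 fibroblast list members 3, were at least 4-fold higher in all knock-in libraries than in any wild-type library. Cxcl10 lay at 43.7 to 288 FPKM against 3.39 to 5.80, and Lox, a collagen crosslinking enzyme gene, at 52.9 to 215 against 1.49 to 3.29. Macrophage markers were present in both lines. Emr1, which encodes the macrophage protein F4/80, was at 4.70 to 6.44 FPKM in wild-type libraries, 36.46 to 36.47 in vehicle and 48.03 to 57.8 in dox, and C1qa, a complement gene of macrophages, at 14.4 to 19.4, 32.3 to 34.9 and 70.1 to 82.9. Of 14 measured macrophage markers, 8 rose in dox by the limma test and none fell, with a median of 0.49.

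Fibroblast genes rose and Dnmt3b and Dnmt3l fell in the dox libraries. A smaller share of pluripotent cells would lower their genes alike, but the naive and core list of 26 genes had a median of -0.0791 and a lower quartile of -0.376, above 0.5 of the Dnmt3b change (-0.749). This argues against such a share only as the whole cause of the Dnmt3b fall. In that list 6 genes rose and 7 fell, so a smaller loss of pluripotent RNA stays possible and was not tested. More feeder cells of an unchanged profile would raise their genes alike where the iPSCs do not express them. Of the 16 fibroblast markers lower by 0.5 or more in all 3 siRNA libraries, 37.5% lay over 0.5 and over 3 SE from their median dox difference of 1.65, from Mgp at 0.35 to Dcn at 2.98. Outside these 16, Tagln fell by 0.33, though not without vehicle clone 1 or vehicle clone 2, and Acta2 differed by -0.01, and neither was lower by 0.5 in any siRNA library. For the fibroblast rises, such feeder cells and a changed feeder profile cannot be told apart, because expression of these markers in the iPSCs, which would shrink a rise, is unknown. A contribution of feeder RNA may still be part of it, since 68.9% of the 280 genes higher in both dox clones were lower in all 3 siRNA libraries than in siControl, against 20.7% to 30.7% of matched random lists and 91.4% of the fibroblast list, with Col1a1 at 505 FPKM in dox. That share is partly built in, since the 280 genes include fibroblast markers such as Dcn. All 3 siRNA comparisons also share the same siControl library, and the random lists were matched on expression only. A changed feeder population and an effect of dox or miR-203 within the iPSCs stay open as untested, and no library without feeder cells was analysed here.

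The double siRNA differences from siControl were spread more widely than those of the single siRNAs, with an SD of 0.245 (log2) over 11928 genes against 0.16 and 0.135. They followed GC content (Spearman's rho 0.485) and transcript length (-0.481), across genes. After the correction for both, the SD was 0.201, against 0.156 and 0.131 for siDnmt3a and siDnmt3b. Corrected the same way, it was 0.201 between the dox clones and 0.195 between the vehicle clones. The trends, as corrected here, may account for part of the excess over the single siRNAs but not for all of it. The width left lay near that between clones of the same group, so it is not by itself a sign of the double siRNA. An effect of the double siRNA stays open and was not tested, with 1 library.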
